A study of Mus musculus with 15 samples.

How the data were processed

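Cerebellum RNA of 15 mouse samples was measured by bulk RNA sequencing. Per the labels' protocols, RNA was extracted from flash-frozen cerebellum, ribosomal RNA was depleted, stranded mRNA libraries were prepared and paired ends were sequenced. The deposited table holds whole-number counts of reads per gene, not normalized, with 1 column per library and no pooling of replicates. It has 55487 mouse genes named by Ensembl identifiers. Per the submitters' processing notes the tools included STAR and the genome build was GRCm39. The counting tool, its treatment of strand and of reads that map to several places, and the gene annotation are not given in the sources used here. Reads of overlapping, antisense and near-identical genes can therefore not be told apart with certainty. Gene symbols were taken from GENCODE release M21, an annotation of the earlier GRCm38 build, by the identifier, and 55141 identifiers (99.4%) had a match. Since that build differs from the authors' build, no coordinates are given.

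Groups and batches (A or B) were taken from the labels. The groups were edited transplant (mPPL-001, n = 5), mock transplant (n = 4), untreated YG8JR (n = 3) and wild type (WT, n = 3). Batch A held 8 libraries and batch B held 7, and each group had libraries in both. The labels do not state in so many words that every sample came from a separate animal, so p-values measure the spread between these samples. Pairs of libraries of 1 group were checked for duplicates by a chi-square test of their counts. The smallest value was 23.2 per gene, so no library was counted as a copy of another. Library totals ran from 16847875 to 38760543 counts. CPM values, in which each library is scaled to the same total, were computed from the counts with library sizes scaled by TMM normalization.

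The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with robust estimation. One model with a mean for each group and a batch term was fitted to all 15 libraries, so that all groups shared 1 estimate of the spread. Genes with too few counts were removed by the edgeR filter (minimum count 10, minimum total 15), which left 24990 genes. The common dispersion was 0.11, a biological coefficient of variation of 0.332. P-values were adjusted by the Benjamini-Hochberg method and genes with an adjusted p under 0.05 were called changed. Standard errors are those of the log2 fold change, and spreads of CPM are standard deviations between libraries.

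Before the data were examined, 46 gene lists were fixed, together with the groups, the tests, the alternatives and the rule for named genes. The lists covered cell types of the cerebellum and of neighbouring or contaminating tissue, immune states, mitochondrial and iron biology, stress, and RNA quality. Lists were tested with camera (limma 3.58.1) on voom values with a preset correlation between genes of 0.01. The same test with a correlation estimated from the data was run beside it. P-values were adjusted over the 46 lists within a comparison. Members past the threshold were counted after adjustment over all genes and adjusted over the list alone. Genes higher or lower in untreated YG8JR than in WT were also tested as sets in the comparison of the transplants. Where a direction had fewer than 20 called genes, the 100 genes of that direction with the smallest p were used.

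Named genes followed a fixed rule. In each of the first 4 comparisons, up to 10 called genes per direction with the largest fold change and a mean of at least 1 CPM in the higher group were named, leaving out predicted genes without a proper name. Up to 4 members of each list with the smallest p could be added. In a direction with fewer than 5 calls, the 5 genes with the smallest p under the same filters were named. For the comparisons of the transplanted groups with WT, 5 genes per direction were named. The satellite-like genes were named outside this rule, after their values were seen. Results for some genes are not reported here, among them part of the evidence on the label of WT replicate 3.

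Alternatives were another normalization (RLE), no low-count filter, a stricter filter, DESeq2 1.42.0, no batch term, the replicate number as a block, a fit of only the groups compared, differences within each batch, the level of Y-linked transcripts as a covariate, voom with sample weights, and each library left out in turn. After seeing the data, a covariate for brain region and a fit with WT replicate 1 as the only wild-type library were added. The region score was the mean log2 CPM of the granule and Purkinje lists minus that of the brainstem list.

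The count tests were tested on simulated data with 200 changed genes among about as many genes as in the real data. The changed genes were drawn from those with a mean over 1 CPM, in a single run for each comparison. Each gene was simulated on its own. The shares recovered may therefore not hold for genes of lower level or for genes that vary together. For mPPL-001 against mock, edgeR recovered 58% of genes changed 2-fold and 92% of those changed 4-fold, with 5 false calls among 24472 genes. For untreated YG8JR against WT it recovered 32% and 76%, with 2 false calls among 24502 genes. For mPPL-001 against untreated YG8JR it recovered 42% and 79%, with 9 false calls among 24490 genes. For mock against untreated YG8JR it recovered 48% and 86%, with 8 false calls among 24458 genes. DESeq2 made 46, 35, 60 and 37 false calls in these 4 comparisons, so genes that passed with DESeq2 and not with edgeR are less certain. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.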

Results

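Bulk RNA sequencing was done on the cerebellum of YG8JR mice, a model of Friedreich ataxia, and of wild-type (WT) mice. One group of YG8JR mice (n = 5) had received mPPL-001, hematopoietic stem and progenitor cells (HSPCs) from YG8JR marrow electroporated with Cas9 and a pair of guide RNAs. Another group (n = 4) had received mock HSPCs, electroporated with the guides and without Cas9. Both were irradiated with 7 Gy at an age of 2.5 to 3 months and received antibiotics for 1 month. The series examined tissue 6 months after transplant, beside untreated YG8JR mice (n = 3) and WT mice (n = 3). The stated aim was to evaluate neuroprotection by mPPL-001. Library totals were 21572184 to 37719880 counts for mPPL-001, 29064915 to 38760543 for mock, 34814367 to 37972796 for untreated YG8JR and 16847875 to 37210466 for WT.

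The library labelled WT replicate 3 lay close to the YG8JR libraries of its batch. Its deviation from 7 YG8JR libraries of batch A was regressed on the WT difference of batch B over 6374 genes, where a slope of 1 means the full difference. The slope was 0.14, inside the range of those YG8JR libraries themselves (-0.31 to 0.36). Single genes differed in this, as the microglial gene Clec7a stood at 0.4 CPM in that library against 0.201 and 0.454 CPM in the other WT libraries and 1.14 to 5.83 CPM in all 12 YG8JR libraries. Cybb, the oxidase subunit of phagocytes, stood at 0.933 CPM in it against 0.955 and 1.01 CPM in the other WT libraries and 2.2 to 10.3 CPM in all 12 YG8JR libraries. The complement gene C4b stood at 70.4 CPM in it, between the other WT libraries (12.4 and 34.2 CPM) and untreated YG8JR (170 to 240 CPM). Clec7a and Cybb were called higher than in WT in fits that counted this library as WT, which favoured a low level in it. Of the 46 gene lists, 10 scored in it below all 7 YG8JR libraries of batch A and 3 above. By more than the range of those libraries, 0 lists lay below. Lists of microglia, macrophage, complement and interferon genes were among those that scored below. Every direction drawn from WT below carries a doubt about the label of this library.

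Granule and Purkinje neuron transcripts separated the batches in every group. Gabra6, a GABA receptor subunit of granule neurons, ran from 0.0586 to 71.9 CPM in batch A (n = 8) and from 206 to 504 CPM in batch B (n = 7). Pcp2, a Purkinje cell gene, ran from 0.193 to 24.4 CPM in batch A and from 21.2 to 71 CPM in batch B. Slc6a5, the glycine transporter of brainstem and deep cerebellar neurons, averaged 474 ± 294 CPM in batch A and 66.5 ± 26.7 CPM in batch B, but within mPPL-001 it ran from 43.2 to 631 CPM in batch A (n = 3) and stood at 68.6 and 96.7 CPM in batch B. Chat, of cholinergic neurons, averaged 16.2 ± 7.8 CPM in batch A and 0.838 ± 1.46 CPM in batch B. Between batches 4509 genes were higher in B and 3714 lower. The batch term was kept in the model for this reason, and within-batch values are given where a list did not keep its direction. Batch A held 1 WT library and batch B 1 untreated YG8JR library, so within-batch tests of these groups rest on a lone library, assumed to vary like the others. Sex, which the labels do not give, was uneven between groups. Y-linked transcripts summed to 0.035 to 1.63 CPM in mock replicates 1 and 4, YG8JR replicate 3 and WT replicates 1 and 2, and to 198 to 253 CPM in the other libraries.

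**Figure D1:**
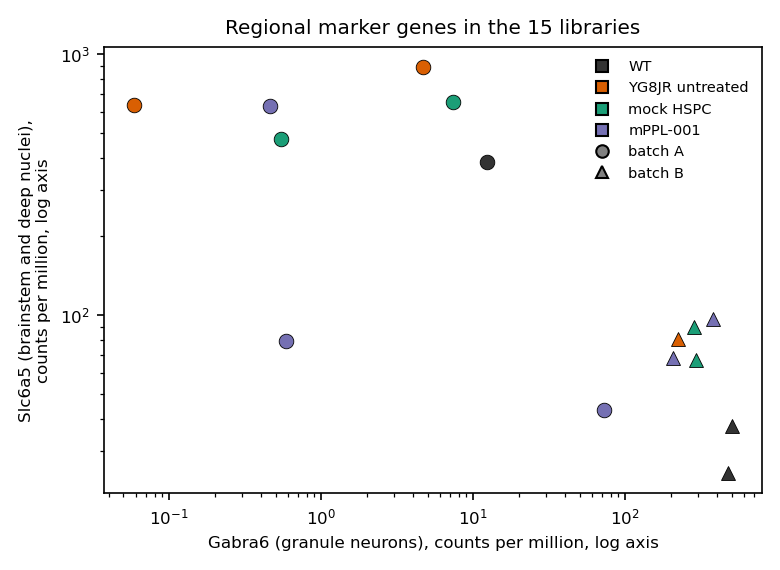
Gabra6 against Slc6a5 in the 15 libraries, both in CPM on log axes, with colours for groups and symbols for batches. The 7 batch B libraries lie at 206 to 504 CPM of Gabra6 and the 8 batch A libraries at 0.0586 to 71.9 CPM.

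Untreated YG8JR and WT mice were compared to ask how the cerebellum of the model differed without a transplant. Genes of microglia and immune function were among those higher in YG8JR. Clec7a (ENSMUSG00000079293.11), a receptor of activated microglia, stood at 4.07 ± 0.634 CPM against 0.352 ± 0.133 CPM in WT (n = 3 each, log2 fold change 3.56, SE 0.48, edgeR adjusted p = 0.0153). Gpnmb, a glycoprotein of phagocytic microglia, was higher by a log2 fold change of 2.56 (SE 0.43), C3ar1, the receptor of complement C3a, by 1.76 (SE 0.25) and the lymphocyte receptor gene Ly9 by 3.24 (SE 0.49). Cx3cr1, the fractalkine receptor of microglia, was higher by 1.30 (SE 0.16), Cd68, a lysosomal protein of phagocytes, by 1.70 (SE 0.26), Cybb by 1.61 (SE 0.28) and the MHC class I gene H2-K1 by 1.21 (SE 0.22). Among other genes, Nes (nestin) was higher by 2.05 (SE 0.26), the stress-response genes Nupr1 and Atf5 by 2.12 (SE 0.32) and 1.52 (SE 0.26), Cd93, an endothelial gene on the complement list, by 1.97 (SE 0.29), Edn3 (endothelin 3) by 1.81 (SE 0.26), Pgm5 by 1.75 (SE 0.24) and the transcription factor gene Dmbx1 by 3.76 (SE 0.67). Lower in YG8JR were Grb7 (-1.69, SE 0.28), the prostaglandin transporter gene Slco2a1 (-1.59, SE 0.29), Crhr1, the receptor of corticotropin-releasing hormone (-1.13, SE 0.18), and the phosphatase gene Ptpru (-0.82, SE 0.14). In all, 30 genes were higher and 6 lower of 24990 tested by edgeR at an adjusted p under 0.05, and 6318 genes (25.3%) had an unadjusted p under that value. No gene passed within batch A, within batch B, in a fit of these 6 libraries alone or without YG8JR replicate 2, and 6, 10 and 18 passed without YG8JR replicate 1, YG8JR replicate 3 and WT replicate 1. The within-batch tests set 2 YG8JR libraries against 1 WT library in batch A and 1 against 2 in batch B, and all 36 genes kept their sign in both. Without the library labelled WT replicate 3, 4096 genes passed, including all 36, each in the same direction. The WT libraries left were replicates 1 and 2, both of batch B and nearly without Y-linked transcripts. The 1 untreated YG8JR library of batch B had such transcripts, so genotype and sex cannot be told apart within that batch. The rise in calls can therefore not be credited to the label of the dropped library alone.

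**Figure D2:**
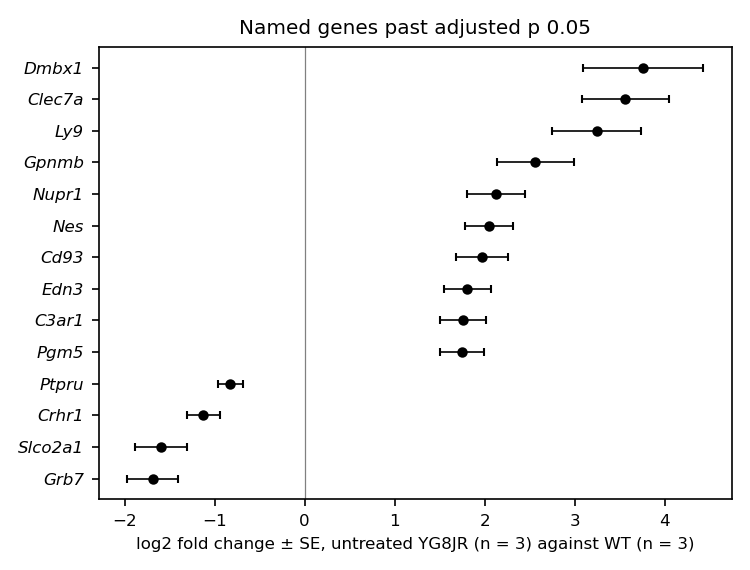
Log2 fold changes ± SE of the named genes past the threshold in untreated YG8JR (n = 3) against WT (n = 3). They run from 3.76 for Dmbx1 to -1.69 for Grb7.

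Glial, endothelial and immune lists fixed before the data were examined had positive medians in this comparison, with the label doubt above. All 25 measured genes of homeostatic microglia had positive fold changes (median 0.99), of which 1 passed over all genes and 20 adjusted over the list alone (camera adjusted p = 2.22e-14). Within this list Ctss, a lysosomal protease, had a log2 fold change of 1.73 (adjusted p = 0.0885) and C1qc, of the first complement component, 1.57 (adjusted p = 0.104). All 23 genes of MHC class I presentation and complement were positive (median 1.11, 3 passing, 16 adjusted over the list alone, camera adjusted p = 1.12e-12). The complement gene C4b had 2.33 (adjusted p = 0.0549). Of 25 genes of disease-associated microglia 23 were positive (median 1.06, 4 passing, 18 adjusted over the list alone). Astrocyte markers were positive in 15 of 15 (median 0.84, 14 adjusted over the list alone), with Gfap at 812 ± 326 against 202 ± 158 CPM (n = 3 each) and Sox9 at 0.94. Endothelial genes were positive in 18 of 18 (median 0.88, 12 adjusted over the list alone), with 1.37 for the tight-junction gene Cldn5 and 1.11 for Pecam1. Interferon response genes were positive in 38 of 39 (median 0.83), with 9 higher and 1 lower adjusted over the list alone and Ifih1 at 1.08. With an estimated correlation no list passed: adjusted p = 0.309 for the microglia, complement, disease-associated, astrocyte and endothelial lists, and adjusted p = 0.342 for interferon. Genes of mature oligodendrocytes (21 of 21 positive, median 0.64, camera adjusted p = 1.52e-08) and of their precursors (14 of 16, median 0.64, camera adjusted p = 2.52e-06) had positive medians too, and passed with an estimated correlation in neither case (adjusted p = 0.342 and 0.309). Brainstem genes were positive in 16 of 23 (median 0.69) and did not pass (camera adjusted p = 0.21). Slc6a5 averaged 764 CPM in YG8JR against 386 CPM in WT in batch A (n = 2 and 1) and 80.8 against 31.1 CPM in batch B (n = 1 and 2). With the region score as covariate the medians were 0.96 for microglia, 1.07 for complement, 0.77 for astrocytes, 0.80 for endothelium and 0.68 for interferon, still past the threshold with the preset correlation. Within batch A they were 0.65 for microglia, 0.50 for disease-associated microglia, 0.46 for astrocytes and 0.52 for interferon. WT replicate 2 stood apart in these lists, with mean scores of -1.56 for microglia and -1.59 for astrocytes against -0.69 and -0.46 in WT replicate 1. On the lists of ribosomal genes and nuclear RNAs WT replicate 2 scored -0.87 and 1.08, against -0.02 and 0.51 in WT replicate 1. Of all libraries WT replicate 2 had the fewest counts (16847875), and its voom weight was 0.204. Without it the medians were 0.88 for microglia, 1.00 for complement, 0.93 for disease-associated microglia, 0.64 for astrocytes, 0.72 for endothelium and 0.60 for interferon, all still past the threshold by camera with the preset correlation.

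Mitochondrial and iron genes showed small positive values in untreated YG8JR. Mitochondrially encoded transcripts made up 1.94% and 1.54% of counts in WT replicates 1 and 2 and 3.26% in the library labelled WT replicate 3. They made up 3.02% to 3.45% in untreated YG8JR and 2.88% to 5.59% over all YG8JR libraries, transplanted ones included. Of 77 nuclear genes of oxidative phosphorylation 75 were positive (median 0.42, camera adjusted p = 3.86e-11) with 0 passing adjusted over the list alone, and adjusted p = 0.416 with an estimated correlation. That median was 0.22 without WT replicate 2, 0.67 without the library labelled WT replicate 3 and 0.15 within batch A. Of 41 genes of iron-sulphur cluster assembly, haem and iron handling 33 were positive (median 0.33, 0.21 without WT replicate 2, 0.15 within batch A, camera adjusted p = 0.000116, 0 adjusted over the list alone, adjusted p = 0.371 with an estimated correlation). Among these, the ferroxidase gene Cp had 1.04 (adjusted p = 0.122), the iron exporter gene Slc40a1 0.81 (adjusted p = 0.125) and the ferredoxin reductase gene Fdxr -0.58 (adjusted p = 0.136). Cp had 1.63 without the library labelled WT replicate 3 and Fdxr -0.34 without WT replicate 2. The list of the integrated and mitochondrial stress responses had 26 of 30 positive (median 0.54, 2 passing, 8 adjusted over the list alone, camera adjusted p = 1.19e-08, adjusted p = 0.309 with an estimated correlation). Granule neuron markers were negative in 19 of 19 (median -0.93, camera adjusted p = 9.31e-06, 2 adjusted over the list alone, adjusted p = 0.342 with an estimated correlation), with Slc17a7 at -1.58 (-0.93 without the library labelled WT replicate 3) and Grm4 at -1.05. Purkinje cell markers were positive in 20 of 20 (median 0.53, adjusted p = 0.00212, and adjusted p = 0.525 with an estimated correlation), but their median was -0.16 within batch A, against the library labelled WT replicate 3 alone, and 1.21 within batch B, with 1 YG8JR library. It was 0.08 without YG8JR replicate 1 (adjusted p = 0.0798), 0.81 without YG8JR replicate 3, 0.31 without WT replicate 2 and 0.92 without the library labelled WT replicate 3. By camera with the preset correlation 30 of 46 lists passed.

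Mock-transplanted and untreated YG8JR mice were compared to show what irradiation, antibiotics and transplant did without the edit. The 9 genes called were all predicted genes without a proper name, all higher after mock transplant, and all resembled satellite repeats, the tandem DNA of centromeres. They were singled out after their values were seen. Of 12 such genes, 9 had transcripts that matched themselves best at a shift of 234 bases, with 61.7% to 67.6% of bases alike. Gm10801, Gm10800 and Gm11168 matched best at 231, 225 and 237 bases, with 52.7%, 56.3% and 62.9% alike. Over all 12 genes, 34.3% to 89.3% of the 31-base words of a gene occurred in another of the 12. Gm10801 (ENSMUSG00000075015.3) had a log2 fold change of 3.79 (SE 0.27, adjusted p = 9.6e-06, edgeR), Gm10800 had 4.10 (SE 0.43), Gm10718 had 4.33 (SE 0.30) and Gm10715 had 5.08 (SE 0.67). The summed level of 12 such genes was 961 ± 147 CPM after mock (n = 4) against 66.5 ± 20.8 CPM in untreated YG8JR (n = 3). Because they share sequence, reads can be split among them and single values are uncertain. By edgeR 0 genes were lower and 389 of 24990 had an unadjusted p under 0.05, whereas DESeq2 gave 12 higher and 3 lower genes and voom with sample weights 10 and 0. In simulated data of this comparison DESeq2 made 37 false calls and edgeR 8. Among the lower genes with the smallest p were Ano2, Htr5b, Trh (thyrotropin-releasing hormone) and the microglial gene Siglech, at -4.95, -3.86, -3.89 and -0.96 (edgeR adjusted p = 0.287 for Ano2 and 1 for the others). Ano2 passed with DESeq2 (adjusted p = 1.71e-06), within batch A (0.00795) and without YG8JR replicate 1 (0.00091), and Htr5b with DESeq2 (0.0274) and without YG8JR replicate 1 (0.0198). Within batch B the first 3 of these had -0.57, 0.09 and -0.53, and Trh had -2.40 without YG8JR replicate 3.

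**Figure D3:**
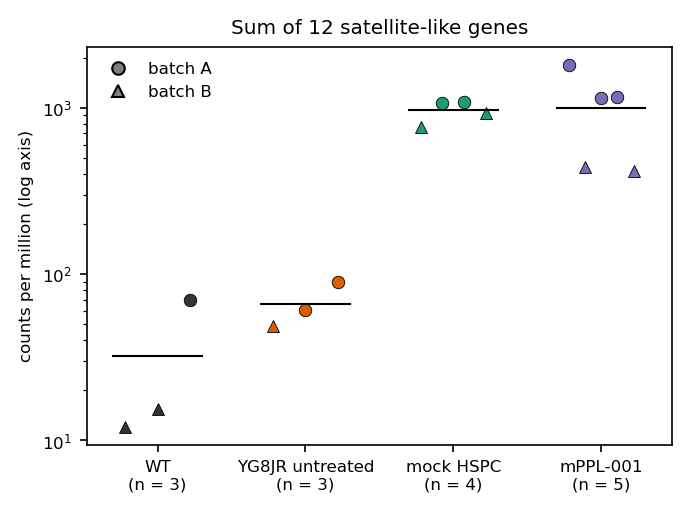
Summed CPM of 12 satellite-like predicted genes in each library on a log axis, by group, with circles for batch A and triangles for batch B. Horizontal lines are group means. The 9 transplanted libraries lie at 418 to 1801 CPM and the 6 others at 12.1 to 89.5 CPM.

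Immune lists had medians of both signs after mock transplant. Genes of marrow-derived and border macrophages were positive in 21 of 26 (median 0.58, camera adjusted p = 1.94e-10), with 9 higher and 1 lower adjusted over the list alone and 0 over all genes, and a median of 0.34 without mock replicate 4 and 0.29 within batch A. Ms4a7, a marker of marrow-derived macrophages in brain, stood at 1.41 ± 0.477 against 0.42 ± 0.0835 CPM (log2 fold change 1.64, SE 0.39, n = 4 and 3), the MHC class II genes H2-Aa and Cd74 had 1.73 and 1.71, and the lysozyme gene Lyz2 had 1.19. Homeostatic microglia genes were negative in 21 of 25 (median -0.26, camera adjusted p = 5.82e-10), with -0.48 for Cx3cr1 and -0.56 for P2ry12, and 0 passed over the list alone. Their median was -0.46 without mock replicate 4 and -0.42 without YG8JR replicate 3. Interferon response genes were positive in 34 of 39 (median 0.31, camera adjusted p = 1.58e-06), with Iigp1 at 1.18 (0.77 without mock replicate 4), but the call ended without mock replicate 4 (median 0.11, adjusted p = 0.231) and within batch B, with 1 YG8JR library (median 0.07, adjusted p = 0.962), and the median was 0.54 without YG8JR replicate 1 and 0.18 without YG8JR replicate 3. Fibroblast genes were positive in 17 of 18 (median 0.59, camera adjusted p = 1.94e-10) and choroid plexus genes in 19 of 19 (median 1.93, camera adjusted p = 5.82e-10), the latter with Kcnj13 at 1.98 (1.17 without mock replicate 3). The fibroblast median was 0.95 without YG8JR replicate 1, 0.36 without YG8JR replicate 3 and 0.22 within batch B, and the choroid plexus median was 0.64 without mock replicate 3. Slc13a4, on the fibroblast list, had 1.71. Ttr, the dominant transcript of choroid plexus, stood at 2812, 3649 and 2618 CPM in mock replicates 1, 3 and 4, at 4.86 CPM in mock replicate 2, and at 2.7 to 576 CPM in untreated YG8JR. Genes of the p53 and DNA damage response were positive in 19 of 26 (median 0.08, camera adjusted p = 0.0108), with Eda2r at 1.36, but that call ended within batch A (adjusted p = 0.239), with no low-count filter (0.131), with the replicate block (0.0572) and without mock replicate 4 (0.158) or YG8JR replicate 1 (0.476), and its median was 0.05 without mock replicate 4 and 0.21 without YG8JR replicate 3. Iron and iron-sulphur genes had a median of 0.01 (23 of 41 positive, adjusted p = 0.997), from -0.06 without mock replicate 3 to 0.05 without YG8JR replicate 2, and the list test changed direction in 7 of 18 alternatives. Bmp6, on this list, had 0.87. With an estimated correlation no list passed: adjusted p = 0.747 for the macrophage, microglia, fibroblast, choroid plexus and p53 lists, and adjusted p = 0.952 for interferon. Every single gene in this paragraph had an edgeR adjusted p = 1 over all genes, and H2-Aa passed with DESeq2 (adjusted p = 0.0434).

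Edited transplants and untreated YG8JR mice were compared to show what the edited graft and its conditioning changed. The 8 genes called were again satellite-like, and all higher after mPPL-001. Gm10801 had a log2 fold change of 3.8 (SE 0.26, adjusted p = 1.44e-05, edgeR), Gm10800 had 3.77 (SE 0.42) and Gm10715 had 4.73 (SE 0.66), and the summed level was 991 ± 579 CPM (n = 5) against 66.5 ± 20.8 CPM (n = 3). All 8 were also among the 9 genes of the mock comparison, where 0.00288 shared genes would come from independent lists and 0 came from 20 simulations of unchanged groups against these controls. By edgeR 0 genes were lower and 836 had an unadjusted p under 0.05, whereas DESeq2 gave 16 higher and 6 lower genes and voom with sample weights 13 and 13. In simulated data of this comparison DESeq2 made 60 false calls, edgeR 9 and voom 10. Across genes the fold changes of both comparisons correlated at r = 0.639, against a mean of 0.602 in the simulations (0.581 to 0.618), and their covariance was 0.162 against a simulated 0.145, a difference of 0.0176. The simulated groups held no changed genes, so an overlap of 0 there does not show what shared controls add among called genes. Each gene was drawn on its own in the simulations, so their range of r may be too narrow as a reference. The 3 control libraries are too few to split, so part of the excess in shared genes may come from sharing them. Of the lower genes with the smallest p, the hormone gene Gh had -5.64, Htr5b -4.94 and Ano2 -4.67 (edgeR adjusted p = 0.263, 0.066 and 0.275). With DESeq2 Htr5b and Ano2 passed (adjusted p = 1.93e-05 and 2e-06). Gh, Htr5b and Ano2 passed within batch A (0.00673, 0.0142 and 0.000624), and Htr5b and Ano2 without YG8JR replicate 1 (0.00111 and 0.00105). Within batch B, with 1 YG8JR library, the values were -1.21 for Gh, -1.29 for Htr5b and 0.64 for Ano2. Scores of the brainstem list also differed within batch A. They were 1.50 and 2.20 in untreated replicates 2 and 3, and 1.23, 0.50 and 0.54 in mPPL-001 replicates 1, 3 and 4. In mock replicates 2 and 3 they were 1.97 and 2.08. A lower level of these genes after mPPL-001 cannot be told apart from such differences between samples. The hormone gene Prl was among these genes too (adjusted p = 0.379 by edgeR and 0.000211 by DESeq2). It stood at 156 CPM in untreated replicate 3 alone, at 0.847 CPM or lower in the other untreated libraries and at 0 to 0.0836 CPM after mPPL-001, so its fold change has no fixed size.

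Lists of resident microglia and of marrow-derived and border macrophages had medians of opposite sign after mPPL-001 as well. The macrophage list does not tell marrow-derived from border cells. Homeostatic microglia genes were negative in 21 of 25 (median -0.37, camera adjusted p = 8.33e-16, 5 lower adjusted over the list alone). Cx3cr1 stood at 25.3 ± 4.86 against 41.9 ± 12.7 CPM (log2 fold change -0.66, SE 0.14, adjusted p = 0.383), and P2ry12, Siglech and Gpr34 had -0.73, -1.04 and -0.80 (adjusted p = 0.966 each). Macrophage genes were positive in 17 of 26 (median 0.31, camera adjusted p = 0.0046, 4 higher adjusted over the list alone). Of the mPPL-001 libraries, replicate 5 scored highest on this list (0.68) and on the choroid plexus list (2.52). Mock replicate 2 scored 0.44 and -1.41 on these lists and mock replicate 3 scored 0.17 and 2.25. A link between macrophage values and choroid plexus in the samples was not tested. Ms4a7 stood at 2 ± 0.596 against 0.42 ± 0.0835 CPM (log2 fold change 2.19, SE 0.38, adjusted p = 0.0929 by edgeR), and Lyz2, Clec12a and Mrc1 had 1.40, 2.05 and 0.91 (adjusted p = 0.966 each), with Clec12a at 3.33 without YG8JR replicate 3. Ms4a7 passed with DESeq2 (adjusted p = 7.21e-05) and with voom (0.0409), Cx3cr1 with DESeq2 (0.0171) and Lyz2 with voom (0.0345). The macrophage list lost its call within batch A (median 0.21, adjusted p = 0.231), with the replicate block (0.11, adjusted p = 0.194), without mPPL-001 replicate 5 (0.14, adjusted p = 0.0785) and without YG8JR replicate 1 (0.24, adjusted p = 0.0733), and its median was 0.64 within batch B. Genes of disease-associated microglia had a median of -0.12 (18 of 25 negative, adjusted p = 0.103), and passed in 6 alternatives, which were no low-count filter (adjusted p = 0.00894), the replicate block (0.034), the 2-group fit (0.0296), the Y-linked covariate (0.00617) and the fits without mPPL-001 replicate 5 (0.0247) or YG8JR replicate 3 (0.0277). The median ran from -0.20 without mPPL-001 replicate 3 to -0.06 without YG8JR replicate 2 and -0.02 without YG8JR replicate 1. Cybb, on this list, had 1.31 (adjusted p = 0.2 by edgeR, 0.000145 by DESeq2 and 0.0207 by voom). Oligodendrocyte genes were negative in 20 of 21 (median -0.31, camera adjusted p = 4.81e-08), with Ermn at -0.53, but within batch B, with 1 YG8JR library, the median was -0.06 (adjusted p = 0.398). Iron and iron-sulphur genes had a median of -0.05 (30 of 41 negative, adjusted p = 0.0243, with Nfs1 at -0.16, or -0.10 without YG8JR replicate 2), which was 0.12 within batch B (adjusted p = 0.0583). That call ended with the stricter filter (adjusted p = 0.127), with the region covariate (0.0705), and without mPPL-001 replicate 1 (0.128), mPPL-001 replicate 4 (0.0912) or YG8JR replicate 2 (median 0.0033, adjusted p = 0.53). The median was -0.12 without mPPL-001 replicate 2, mPPL-001 replicate 3 or YG8JR replicate 1, -0.10 without YG8JR replicate 3 and -0.09 without mPPL-001 replicate 5. The p53 list had a median of -0.01 (-0.088 to 0.004 with each library left out, camera adjusted p = 0.429), with Eda2r at 0.85. Its test changed direction in 2 of 19 alternatives. With an estimated correlation no list passed: adjusted p = 0.684 for microglia, 0.782 for macrophage and oligodendrocyte, and 0.895 for iron genes.

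**Figure D4:**
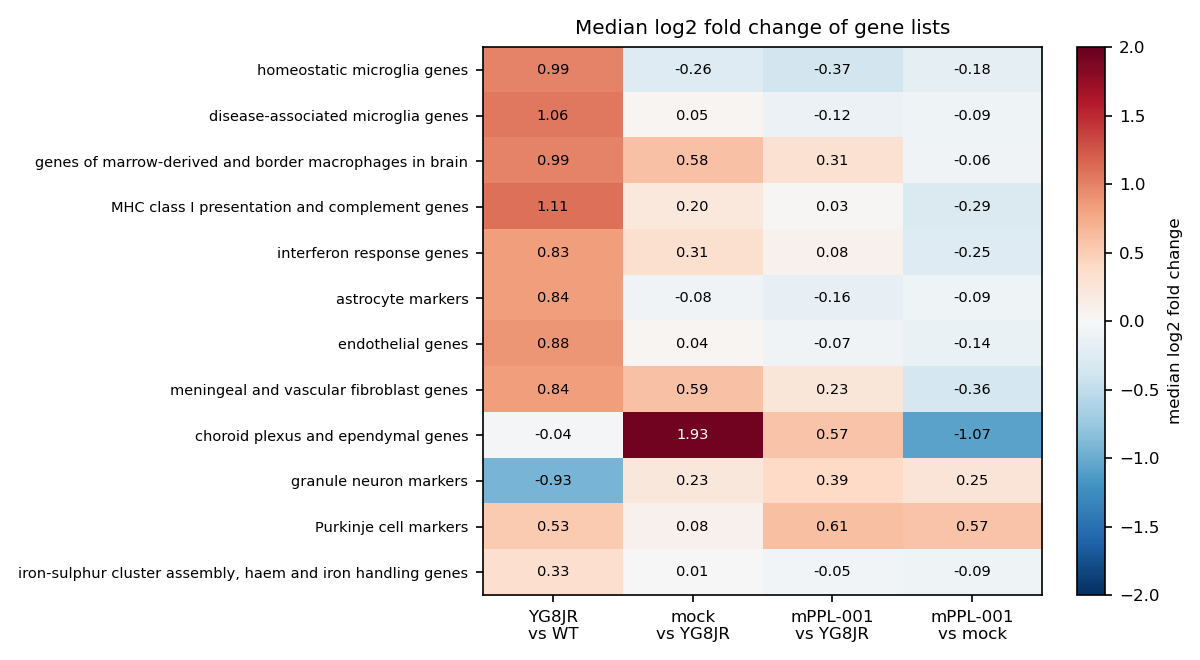
Median log2 fold change of the measured members of 12 gene lists in 4 comparisons, with red for higher and blue for lower in the first-named group. Homeostatic microglia genes stand at 0.99 in untreated YG8JR against WT, at -0.26 after mock and at -0.37 after mPPL-001 against untreated YG8JR.

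Edited and mock transplants, which shared irradiation, antibiotics and transplant, were compared to ask what the edit added. Sex differed with the edit, since all 5 mPPL-001 libraries had Y-linked transcripts and both mock libraries of batch B had little of them, so that within batch B the edit and sex are the same contrast. The 5 genes higher after mPPL-001 with the smallest p were R3hdm4 (0.39, SE 0.11), the glycine receptor gene Glra4 (1.62, SE 0.49), Ankrd63 (4.22, SE 1.28), the transcription factor gene Elk1 (0.50, SE 0.16, and 0.31 without mPPL-001 replicate 3) and the neural stem cell gene Nr2e1 (3.72, SE 1.22). The 5 lower genes were Rln3 (relaxin 3, -6.18, SE 1.24), the growth hormone gene Gh (-4.91, SE 1.07), Itgb3 (-0.77, SE 0.21), Slc22a18 (-1.27, SE 0.36) and Cped1 (-0.63, SE 0.18). Each had an adjusted p = 0.999, the smallest of all genes. By edgeR 0 of 24990 genes passed, 534 (2.14%) had an unadjusted p under 0.05, and DESeq2 and voom with sample weights gave 0 as well.

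Inflammatory and choroid plexus lists had lower values after mPPL-001 than after mock. All 23 genes of MHC class I presentation and complement were negative (median -0.29, camera adjusted p = 1.63e-07), with H2-K1 at -0.37, and without mock replicate 4 these were -0.13 (adjusted p = 0.00101) and -0.22. Interferon response genes were negative in 37 of 39 (median -0.25, camera adjusted p = 7.87e-08), with Ddx58 at -0.40 and Iigp1 at -0.71, but the call ended without mock replicate 4 (median -0.05, adjusted p = 0.0747) and without mPPL-001 replicate 2 (median -0.09, adjusted p = 0.0974), and the median was -0.39 without mock replicate 1, -0.08 within batch A and -0.48 within batch B. Without mock replicate 4 Ddx58 had -0.24 and Iigp1 -0.27. Macrophage genes were negative in 17 of 26 (median -0.06, camera adjusted p = 0.00996), with the MHC class II genes H2-Aa, H2-Eb1 and Cd74 at -1.06, -0.96 and -0.92 (-0.70, -0.52 and -0.52 without mock replicate 4), and that call ended within batch A (adjusted p = 0.272), with the region covariate (0.101) and without mPPL-001 replicate 2 (0.0773), mPPL-001 replicate 4 (0.1) or mock replicate 4 (0.165). Their median ran from -0.17 without mock replicate 3 to -0.02 without mPPL-001 replicate 4. Choroid plexus genes were negative in 18 of 19 (median -1.07, camera adjusted p = 3.28e-10), with Cldn2 at -2.13 and Sostdc1 at -1.99 (-4.35 and -4.24 without mPPL-001 replicate 5, -0.67 and -0.89 without mock replicate 3), and with medians of -1.88 within batch A and -0.27 within batch B, -2.42 without mPPL-001 replicate 5 and -0.28 without mock replicate 3. Iron and iron-sulphur genes were negative in 29 of 41 (median -0.09, adjusted p = 0.0054), with Mms19 at 0.22 and with a median of 0.05 within batch B (adjusted p = 0.311), and that call ended without mPPL-001 replicate 1 (adjusted p = 0.0758), mock replicate 3 (0.0756) or mock replicate 4 (0.102). The iron median was -0.14 without mPPL-001 replicate 2 or 3 and -0.15 without mock replicate 2. With the Y-linked covariate the medians were -0.33 for complement, -0.32 for interferon, -0.17 for macrophage, -1.52 for choroid plexus and -0.14 for iron genes, all with calls kept. In none of these lists did a gene pass adjusted over the list alone. With an estimated correlation no list passed: adjusted p = 0.553 for the complement and choroid plexus lists and 0.589 for the interferon, macrophage and iron lists.

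Genes with higher or lower values in untreated YG8JR than in WT were then followed in the comparison of edited and mock transplants, whose groups hold none of those libraries. The batch term and the spread were fitted on all 15 libraries, however, so both comparisons share them and are not fully independent. Of the 30 genes higher in YG8JR than in WT, 22 had the opposite sign, lower after mPPL-001 than after mock (median -0.18, camera adjusted p = 4.13e-05). Among genes lower in YG8JR the 100 with the smallest p were taken, of which only 6 had been called. Of these 100, 78 had the opposite sign (median 0.15, camera adjusted p = 0.00508). No gene of either set passed adjusted over the list alone. With an estimated correlation neither set passed (adjusted p = 0.304 and 0.58). The set of lower genes had a median of 0.0031 within batch A and 0.03 within batch B, with adjusted p = 0.386 and 0.373. Its call also ended when the set was tested in 1 of the 2-group fits (0.473), with the region covariate (0.41), and without mPPL-001 replicate 1 (median 0.09, adjusted p = 0.0778), mPPL-001 replicate 3 (0.09, 0.101), mock replicate 4 (0.12, 0.212) or WT replicate 1 (0.17, 0.0612). Without mPPL-001 replicates 4 and 5 and the library labelled WT replicate 3 the median was 0.10, 0.24 and 0.23. The median of the higher genes was -0.11 without mock replicate 4 and -0.12 without the library labelled WT replicate 3. Across 24990 genes, which are not independent replicates, fold changes of both comparisons correlated at r = -0.353 and rho = -0.434. Of 100 splits of the mPPL-001 and mock libraries, 15 gave as low an r, so chance is not excluded.

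Both transplanted groups were finally compared with WT, to show what still differed from wild type after transplant, with the label doubt above. All 12 satellite-like genes were higher than in WT in both, by log2 fold changes of 4.28 (Gm10801) to 5.68 (Gm11168) after mPPL-001 and 4.27 to 6.18 for the same genes after mock. Gm10715 is left out of these ranges, since it stood at 0 CPM in all 3 WT libraries and its fold change has no fixed size. Of the genes called, 40 of 58 and 88 of 103 were not predicted genes. After mPPL-001, Ms4a7, Lyz2, Clec7a, Cybb and the macrophage sialoadhesin gene Siglec1 were higher by log2 fold changes of 3.46 (SE 0.43), 3.42 (SE 0.41), 3.04 (SE 0.45), 2.92 (SE 0.27) and 2.57 (SE 0.33). Crhr1 (-1.04), Tead4 (-1.38) and Neurl1a (-0.89) were lower, and Ptpru (-0.62, adjusted p = 0.0643) and Tll1 (-1.03, adjusted p = 0.0664) did not pass. In total 54 genes were higher and 4 lower (edgeR, n = 5 and 3). All 5 mPPL-001 libraries had Y-linked transcripts and WT replicates 1 and 2 had hardly any. Of these 58 genes, 16 were also called with the Y-linked covariate, 9 with the replicate block and 12 in the 2-group fit. All 58 kept their sign in each. The count was 26 without mPPL-001 replicate 2, 27 without mPPL-001 replicate 5, 37 without WT replicate 1, 29 without WT replicate 2 and 1800 without the library labelled WT replicate 3. That last fit left only WT replicates 1 and 2, both of batch B.

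After mock, Clec7a, Lyz2, Ly9, Ms4a7 and H2-Aa were higher by 3.39 (SE 0.46), 3.21 (SE 0.41), 2.98 (SE 0.47), 2.92 (SE 0.43) and 2.74 (SE 0.44). Tead4 (-1.70), the potassium channel gene Kcnk10 (-0.98), Crhr1 (-0.93) and the sodium-proton exchanger gene Slc9a5 (-0.89) were lower. In total 96 genes were higher and 7 lower (edgeR, n = 4 and 3). Of these 103 genes, 5 were also called in the 2-group fit, 13 with the replicate block and 71 with the Y-linked covariate. The count was 65, 57, 67 and 39 without mock replicates 1, 2, 3 and 4, and 66 and 60 without WT replicates 1 and 2. It was 4839 without the library labelled WT replicate 3. That fit left only WT replicates 1 and 2, both of batch B and nearly without Y-linked transcripts.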

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

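Of the tests in this part, the olfactory receptor sum and the regroupings of libraries were written before their values were seen, and all others were chosen after the result was seen. Satellite-like genes were higher in both transplanted groups, and 3 technical sources were weighed. Genomic DNA would also raise genes silent in brain. The summed CPM of olfactory and vomeronasal receptor genes was 0.929 times as high in transplanted as in other libraries (0.817 to 1.18 with each library left out). That sum ran from 53.1 to 155 CPM in transplanted and from 49.2 to 174 CPM in other libraries. A little genomic DNA, which would raise many-copy repeats more than these genes, could be hidden in this spread. The receptor sum thus gave no sign of genomic DNA but does not rule it out. The labelled batches are ruled out as a source, since the median log2 fold change was 4.08 within batch A and 3.44 within batch B. A different split of reads among the summed satellite-like genes alone is ruled out as well. It would leave their sum unchanged, and the lowest transplanted sum was 4.68 times the highest untreated YG8JR sum. Reads moved to these genes from near-identical sequences outside the sum would raise it, so the sum cannot decide on that source. It is left open, as the treatment of reads that map to several places is not given. Irradiation, transplant and the antibiotics given to transplanted animals alone cannot be separated in this design, and any of them may be the source.

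The library labelled WT replicate 3 had an expression profile close to that of YG8JR libraries. A YG8JR animal in place of a WT one may explain it or may not, and this was left open. The slope of this library on the WT difference of batch B was 0.14 over 6374 genes, inside the range of the 7 YG8JR libraries of batch A (-0.31 to 0.36). In this library Cybb, Clec7a and Ms4a7 stood at 0.933, 0.4 and 0.187 CPM, below all 12 YG8JR libraries (from 2.2, 1.14 and 0.328 CPM), and C4b stood at 70.4 CPM. Cybb, Clec7a and Ms4a7 were called higher than in WT in fits that counted this library as WT. That choice favoured a low level in it, so these genes cannot decide the question. Of the 46 lists fixed beforehand, 10 scored in it below all 7 YG8JR libraries of batch A and 3 above. By more than the range of those libraries, 0 lists lay below. Lists that scored below were those of homeostatic and disease-associated microglia, macrophages, cytokines and inflammasome, interferon, complement and endothelium. The rest of them held mitochondrially encoded, mitochondrial stress and p53 genes. Lists that scored above held Y-linked, lipid-handling and glucocorticoid genes. Lists can vary together, and these counts were not set against chance. The WT difference itself was learned from only 2 WT libraries and may include the distance of a single library, which was not tested.

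Granule and Purkinje genes were low and brainstem genes high in batch A. Neighbouring brainstem tissue in the batch A samples may be the source, which no test here decides, as the region score, 6.31 log2 units lower there, is made of the same genes and only describes the pattern. RNA degradation that lowers all neuron genes together would not leave brainstem genes higher, and these scored 3.18 higher in batch A. They are part of the pattern, however, so this is no separate test, and degradation beside another source is not excluded. Genotype or treatment is ruled out as the source, since within every group the lowest batch B library lay at least 2.18 above the highest batch A library.

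Single libraries stood apart from their group in 14 of 120 groups of values tested, all of them from mPPL-001 or mock. Chance gives about 1 in 20 for unrelated, normally distributed values. Many of these values came from related genes and lists, and the groups mixed both batches. The 14 are therefore no measure of an excess over chance. In mock replicate 4 Ifih1 stood at 21.1 CPM (others 13.9 to 14.6), H2-Aa at 14.8 (5.02 to 6.54) and H2-Eb1 at 14.2 (4.61 to 5.88). Slc6a5 stood at 631 CPM in mPPL-001 replicate 1 (43.2 to 96.7 in the others). The choroid plexus score was 2.52 in mPPL-001 replicate 5 (-1.66 to -0.60 in the others), where Cldn2 stood at 25.1 CPM, Sostdc1 at 21.2, Kcnj13 at 13.7 and Slc13a4 at 59.1, and Cd74 at 15.5 (5.44 to 8.29). It was -1.41 in mock replicate 2 (1.96 to 2.25 in the others), where Cldn2 stood at 0.419 CPM. H2-K1 stood at 26 CPM in mPPL-001 replicate 4 (34.4 to 37.2) and Gpr34 at 6.93 CPM in mPPL-001 replicate 3 (4.01 to 4.85). Transcripts of the other sex were seen in transplanted animals, with Xist at up to 3.72 CPM in animals with Y-linked transcripts (up to 0.373 without transplant) and up to 50 Y-linked counts in animals with high Xist (up to 2 without transplant).

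Regrouping the libraries showed how often other splits gave as many calls. The splits were not kept within batch or sex, and their shares were not adjusted for the number of comparisons. For mPPL-001 against untreated YG8JR, 1 of 56 splits (the real one, 8 genes) gave as many calls, a share under 0.05, and the highest other gave 5. For mock against untreated YG8JR, 1 of 35 gave as many (9 genes, highest other 1), again a share under 0.05. For untreated YG8JR against WT, 1 of 10 gave as many (36 genes, highest other 0), which is too few splits to exclude chance. For mPPL-001 against mock, the real count was 0 (highest other 92), which 100 of 100 splits must reach, so regrouping tests nothing for that count. For mPPL-001 against WT, 2 of 56 gave as many as the real 58, a share under 0.05. The other split, mPPL-001 replicate 1 and WT replicates 1 and 2 against the rest, gave 1753. Since a wrong grouping gave far more calls, this count alone does not show a difference between the groups. For mock against WT, 1 of 35 gave as many (103 genes, highest other 0), a share under 0.05. The negative correlation of fold changes between the model and the edit was as low in 15 of 100 splits (real -0.353, lowest other -0.615), so chance is not excluded.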

How the results depend on the processing

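The number of genes called depended most on the settings in comparisons with WT, and the cause was not tested. For untreated YG8JR against WT (36 genes), it was 442 with no low-count filter, 71 with the stricter filter, 2213 with DESeq2 (963 higher, 1250 lower), 908 with voom, 8 with no batch term, 17 with the Y-linked covariate, 17 with the region covariate and 148 with WT replicate 1 alone as wild type. It was 0 with the replicate block, in the 2-group fit, within batch A and within batch B, and 0 to 4096 with each library left out. For mPPL-001 against WT (58), it was 183 with no filter, 655 with DESeq2 (445 higher, 210 lower), 200 with voom, 34 with no batch term, 9 with the replicate block, 12 in the 2-group fit, 7 and 1689 within batches A and B, 17 with the Y-linked covariate, 30 with WT replicate 1 alone, and 26 to 1800 with each library left out. For mock against WT (103), it was 777 with no filter, 243 with the stricter filter, 2648 with DESeq2 (1190 higher, 1458 lower), 1372 with voom, 47 with no batch term, 13 with the replicate block, 5 in the 2-group fit, 6 and 1091 within batches A and B, 57 with the region covariate, and 39 to 4839 with each library left out. For mPPL-001 against untreated YG8JR (8), it was 22 with DESeq2 (16 higher, 6 lower), 26 with voom, 5 with no batch term, 14 and 5 within batches A and B, and 6 to 11 with each library left out. For mock against untreated YG8JR (9), it was 15 with DESeq2 (12 higher, 3 lower), 5 with no batch term, 5 within batch B, and 6 to 11 with each library left out. For mPPL-001 against mock it was 0 in all 21 alternatives. Genes shared by both transplants numbered 13 with DESeq2 and 5 with no batch term. Lists passing fell to 0 with an estimated correlation in all 4 comparisons. For mPPL-001 against untreated YG8JR (22 lists), 14 passed with the stricter filter, 7 within batch B and 13 to 24 with each library left out. For mPPL-001 against mock (27), 11 passed within batch B and 18 to 31 with each library left out. For mock against untreated YG8JR (11), 17 passed with the stricter filter, 19 in the 2-group fit and 7 to 17 with each library left out. For untreated YG8JR against WT (30), 30 to 33 passed with each library left out. Purkinje genes in untreated YG8JR against WT turned direction in the list test with no batch term (median 0.31, adjusted p = 0.911). Iron genes turned within batch B after mPPL-001 against untreated YG8JR (0.12, adjusted p = 0.0583) and against mock (0.054, adjusted p = 0.311). In the set of genes higher in YG8JR the median was -0.18 with an estimated correlation (adjusted p = 0.304), and -0.22 to -0.11 with each library left out. In the set of genes lower in YG8JR it was 0.27 in the 2-group fit (adjusted p = 0.473), 0.0031 within batch A, where the test turned direction (0.386), 0.032 within batch B (0.373), 0.077 with the region covariate (0.41), 0.15 with an estimated correlation (0.58) and 0.086 to 0.24 with each library left out. Libraries of the same replicate number were not more alike than others (r from -0.407 to 0.363 in 19 pairs), and 2 of 15 libraries matched best with 1 of their own number.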

Other observations

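The Xist test below was chosen after the result was seen. Sex-specific transcripts, which the labels do not mention, were looked at in transplanted and other animals. In 7 transplanted animals with Y-linked transcripts Xist, the RNA of the inactive X chromosome, ran from 0.699 to 3.72 CPM, against 0.0273 to 0.373 CPM in 3 animals without transplant. In animals with high Xist, 2 transplanted had 35 and 50 Y-linked counts and 3 others had 1 to 2.

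Donor cells of the other sex in the tissue may be the source of these transcripts. The test left this undecided, with an exact 2-sided permutation p = 0.05 for a difference of 1.66 CPM over 120 permutations (7 against 3 animals). This missed the threshold of an exact p under 0.05. All 7 values lay above all 3 others, so the other regroupings counted in this p had a difference of the opposite sign. A test of the predicted direction alone was not run. The written bound for ruling the source out was any p of 0.05 or more, which was badly chosen, because a p that misses the threshold does not show that the values are alike. By that bound the source would have been ruled out, and the reading as undecided was set after the value was seen. The cutoff that sorted animals by Y-linked transcripts was also changed after a first result. At 1 CPM the exact permutation p was 0.255 (12 libraries, 220 permutations), because mock replicates 1 and 4, with high Xist, fell among the animals with Y-linked transcripts, and 50 CPM was then used.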
